A study of Mus musculus with 6 samples.

How the data were processed

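Polyadenylated RNA was sequenced from primary fibro-adipogenic progenitors of male wild-type mice, the mesenchymal cells of skeletal muscle that can become fibroblasts or adipocytes. Per the labels' protocols, cultured cells received 500 nM prostaglandin E2 (PGE2) or vehicle once per day for 2 days, RNA was extracted with silica columns, and libraries were read as paired ends on a NovaSeq instrument. There were 3 libraries per group. The labels do not say whether the numbered libraries came from separate mice or cultures, so p-values measure the spread between these samples, which may be technical.

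The authors deposited a table of whole-number counts per gene, with an Ensembl identifier and a symbol for each of 41388 genes. The genome build was mm10, per the submitters' processing notes. The aligner, the counter, the strand setting and the annotation release are not given in the sources used here, so values of overlapping, antisense or closely related genes are uncertain. Totals were between 21006044 and 52730962 counts per library, and 3 counts corresponded to between 0.0582 and 0.142 CPM, which are counts scaled to library size. All 37 mitochondrial genes were listed at 0 in every library, so mitochondrial share could not serve as a quality measure. Libraries of 1 group differed by chi-square values of 20.3 to 101 per degree of freedom, so none repeated another within sampling noise.

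Counts were tested with edgeR version 4.0.16 in R version 4.3.3. Genes were kept by filterByExpr, which left 15186, and libraries were scaled by trimmed mean of M values. A robust quasi-likelihood test compared PGE2 with vehicle, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are PGE2 over vehicle on the log2 scale, and errors of fold changes are standard errors. CPM values are means ± SD over 3 libraries.

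The same replicate numbers occur in both groups. Deviations of log2 CPM from the group means were correlated, with the rule, set beforehand, that the numbers pair the samples where every correlation exceeds 0.1. The correlations were computed in the same step as both fits, so the numbers of calls were seen together with them. Same-numbered libraries correlated at 0.621 for number 1, 0.169 for number 2 and 0.422 for number 3. PGE2 library 2 correlated more closely with vehicle library 3, at 0.252. Vehicle library 2 and PGE2 library 3 correlated at 0.145, so a matching that swaps numbers 2 and 3 would also meet the rule. The swapped matching was not fitted. By that rule the numbers were treated as pairing the samples, on evidence from the data and not from the labels, and the fit with the replicate number as a block is given beside the unblocked fit as the paired fit.

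A set of 26 gene lists with 350 members, each matched by Ensembl identifier, was fixed before the data were examined, together with the tests and the rule for named genes. Lists were tested with camera of limma version 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and also with an estimated correlation and with fry. Named genes were the 12 highest and 12 lowest fold changes among genes past the threshold with a mean of at least 5 CPM, groups that did not overlap and a symbol that is not a predicted model, all members of the prostanoid lists, and up to 4 members with the smallest adjusted p of each other list. Further members are named as examples of a group, and these were chosen after their values were seen. Gene positions are from the GENCODE annotation of GRCm38, the assembly also called mm10, which held 97.3% of the identifiers.

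Fold changes followed transcript length. A correction was therefore added after the data were seen, in which a lowess trend on the length of the longest annotated transcript, with a span of 0.3, was fitted per library and added to the edgeR offset. A length was known for 99.4% of tested genes. Other alternatives were DESeq2 version 1.42.0, limma-voom, other scalings and filters, a stricter threshold, a test against a 1.2-fold change and each library left out. GC correction, thinning to equal depth, a myogenic covariate, pairs left out and combinations with the block were chosen after the data were seen.

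The fits were tested on simulated data for PGE2 against vehicle with 200 changed genes. With simulated pair effects on 15000 genes, the unblocked fit recovered 13.64% of 1.5-fold, 50% of 2-fold and 73.85% of 4-fold changes, with 0 false calls among 90. The paired fit recovered 66.67%, 83.33% and 96.92% of those sizes, with 4 false calls among 166. With no pair effects simulated, on 14990 genes, the unblocked fit recovered 33.33%, 60% and 90.62% with 10 false calls among 129. The paired fit then recovered 22.73%, 63.08% and 93.75% with 15 false calls among 131. The simulated pair effects were taken from these libraries under the numbered pairing. Genes were drawn independently and with no length trend, unlike the real data, so these false calls need not carry over to the real counts. A list shifted on purpose was recovered, and 0 of 25 other lists passed. Those lists were random and the simulated genes varied independently. That result therefore does not cover real lists whose members move together, such as G2 and M phase with an estimated correlation of 0.964. Figures were drawn with matplotlib version 3.10.9.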

Results

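The data were gene counts from 6 libraries of cultured muscle fibro-adipogenic progenitors, 3 from cells given vehicle and 3 from cells given PGE2, a lipid mediator that signals through receptors coupled to cyclic AMP and calcium. Totals for vehicle libraries 1 to 3 were 41988251, 21006044 and 42708381 counts, and for PGE2 libraries 45811389, 52730962 and 38150216. The single comparison asks how these cells' own transcripts respond to PGE2. The first principal component held 46% of the variance between libraries and placed vehicle libraries at -41.4, -13.4 and 5.82 and PGE2 libraries at -15, 26.6 and 37.4, so the groups overlapped on it while the PGE2 library lay higher than its vehicle library in all 3 pairs.

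PGE2 raised Il6, a secreted cytokine, from 1.48 ± 0.317 to 13.7 ± 5.32 CPM (SD, n = 3 each), a log2 fold change of 3.18 ± 0.353. The orphan nuclear receptor Nr4a1 rose by 1.91 ± 0.227 and the vitamin D receptor Vdr by 1.54 ± 0.155 on the same scale. The lipid transporter gene Abca8a fell by 1.79 ± 0.147, from 29.4 ± 5.43 to 8.48 ± 0.636 CPM, and the imprinted genes Peg3 and Peg10 fell from 86.2 to 37.5 and from 88.3 to 42.4 CPM. In all, 52 of 15186 genes changed, 32 higher and 20 lower, 27 of them at least 2-fold (edgeR, Benjamini-Hochberg). The paired fit changed 2189 genes, 1049 higher and 1140 lower, 249 of them at least 2-fold, and included all 52 with the same direction.

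Il6 (ENSMUSG00000025746) lies on chromosome 5 at 30013114 to 30019981 of mm10, and its edgeR adjusted p was 0.0394, or 0.000296 in the paired fit. Nr4a1 spans 101254269 to 101274795 on chromosome 15, where Vdr lies at 97854425 to 97910630. Abca8a lies on chromosome 11 at 110025634 to 110095978, and its edgeR adjusted p was 0.0188. Other genes that rose were the serine protease Htra4 (log2 fold change 1.85), the granzyme gene Gzme (1.45), Lmcd1 (1.43), the neutrophil chemokine Cxcl1 (1.29), Relt (1.05), the lactate transporter Slc16a3 (0.99), the retinol dehydrogenase Rdh10 (0.94) and Isyna1 (0.89), the enzyme that makes inositol phosphate. Among genes with a mean of at least 5 CPM, Frem1 (-1.97), Tril (-1.61), Nrep (-1.25), Gcnt1 (-1.18) and the sphingomyelinase Smpd3 (-1.10) fell. So did the proton channel Hvcn1 (-1.01), the clock repressor Bhlhe41 (-0.80), Amot (-0.76) and Clcn5 (-0.67). Car3 had a mean below that level and fell most of the 52 genes (-4.38). It went from 2.35 ± 1.655 to 0.112 CPM, the latter close to the level of 3 counts. Others below that level included Fndc5 (-1.70), Plxdc1 (-1.70) and Scml4 (-1.51). Each of the 52 genes had groups that did not overlap, as did 25.9% of all tested genes. The test favours such genes, so for the 52 this is no separate support. Chance gives 10% on average over all groupings of the libraries. The share under each other grouping was not computed, and it can vary because genes move together.

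**Figure D1:**
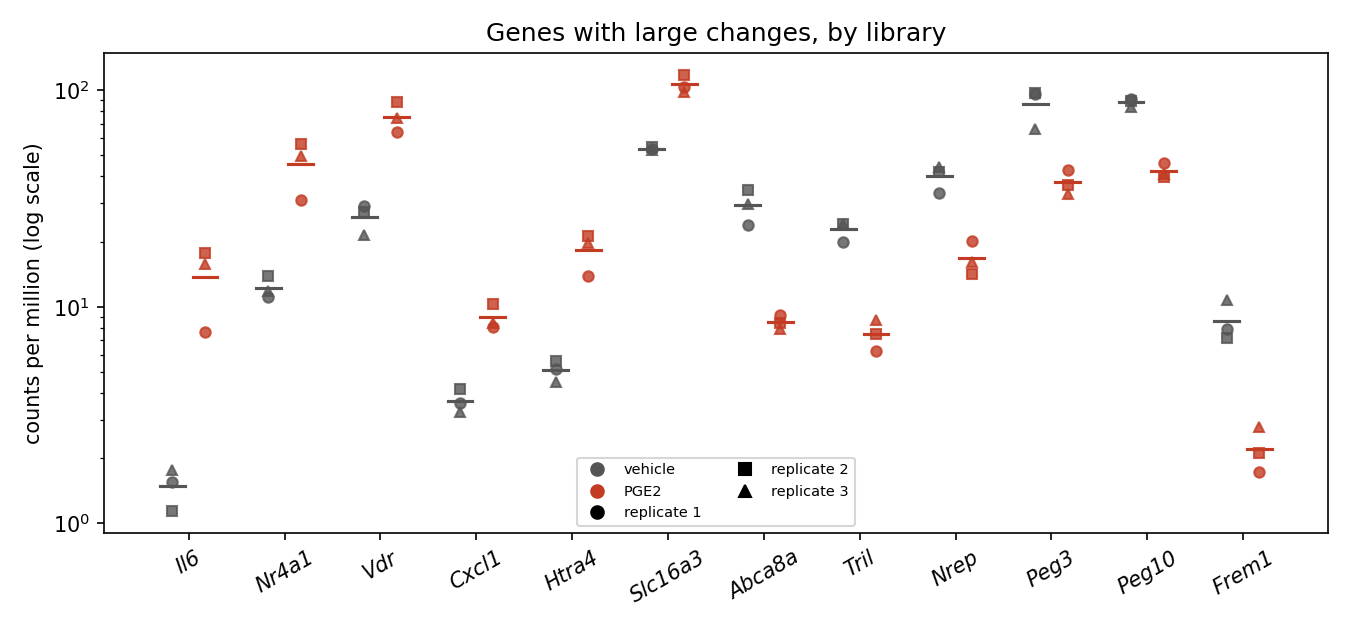
CPM (log axis) of 12 genes past the threshold, with 1 point per library, a horizontal line at each group mean and the marker shape giving the replicate number. Il6 averaged 1.48 CPM under vehicle and 13.7 under PGE2, and Abca8a averaged 29.4 and 8.48. Vehicle and PGE2 points do not overlap for any gene shown, which the rule for naming these genes required.

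The unblocked count was not stable when 1 library was left out, although all 52 genes kept their direction each time. It was 0 without vehicle library 2, vehicle library 3, PGE2 library 2 or PGE2 library 3, with 1871, 3697, 1494 and 2597 genes at an unadjusted p under 0.05, against 3049 with all libraries. It was 30 without vehicle library 1 and 120 without PGE2 library 1. DESeq2 changed 829 genes, 388 higher and 441 lower, and scaling by library totals alone gave 31 higher and 34 lower.

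Longer transcripts were lower under PGE2. Across 10972 genes, which are not independent replicates, the rank correlation of log2 fold change with transcript length was -0.512. With these genes in 5 groups by length, the paired fit had 401 higher and 28 lower in the shortest group, and 51 higher and 494 lower in the longest. The slope per doubling of length differed within pairs by -0.185, -0.204 and -0.0124, so pair 3 showed almost none of it. With the length correction 12 genes passed in the unblocked fit, and the 52 had edgeR adjusted p of at most 0.113; Il6 was at 3.09 (0.0547) and Nr4a1 at 1.84 (0.0561). The paired fit with that correction changed 2576, sharing 1690 with the uncorrected paired fit and including all 52.

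**Figure D2:**
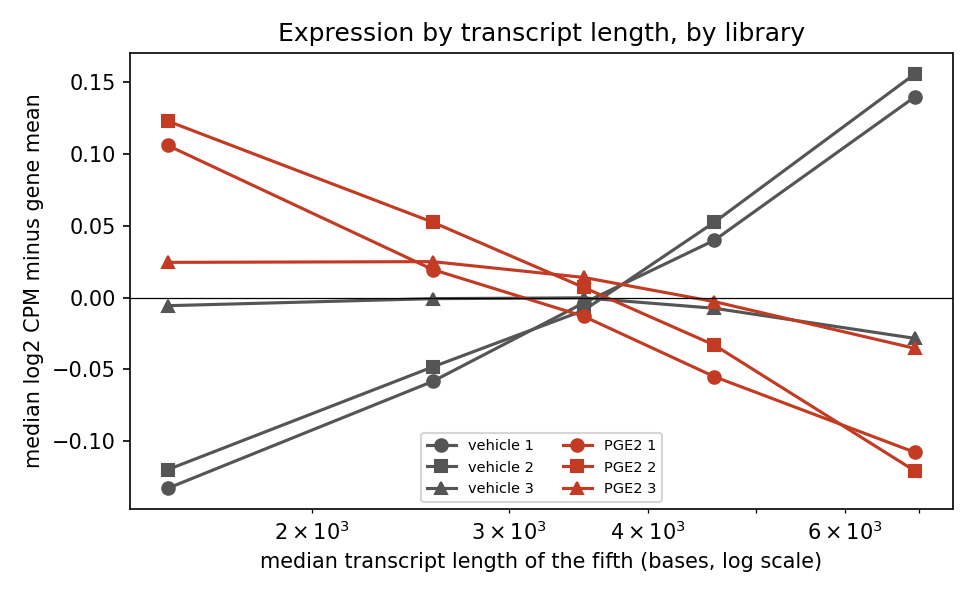
Median deviation of log2 CPM from each gene's mean over 6 libraries, for genes in 5 groups of rising transcript length, against the group's median length in bases on a log axis, with 1 line per library. In the longest group the medians were 0.14, 0.156 and -0.0285 for vehicle libraries 1 to 3 and -0.108, -0.121 and -0.0355 for PGE2 libraries 1 to 3.

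Of 19 tested genes of the cyclic AMP and CREB response, the transcription programme downstream of cyclic AMP, 4 rose, 10 when adjusted over the list alone. The paired fit had 13 higher and none lower, or 15 with the length correction. Among those that did not pass were Fosb (-0.13), Per1 and Ppargc1a (-0.20). Examples were Nr4a1, Nr4a3 (1.89), the CREB family gene Crem (0.84) and the phosphodiesterase Pde10a (0.71). The list moved up by camera (adjusted p = 6.15e-08, paired 2.21e-09, but adjusted p = 0.205 with an estimated correlation), and it still passed with any 1 library left out. Prostanoid receptor genes did not pass the test in either fit: of 7 tested, Ptger4 was at 10.2 ± 0.325 and 9.73 ± 2.73 CPM, Ptger2 at 0.233 and 0.215 CPM, and Ptgfr and Ptgir had log2 fold changes of -0.08 and -0.13. Of 11 prostanoid synthesis and turnover genes 0 passed unblocked, none when adjusted over the list alone, and in the paired fit the cyclooxygenase Ptgs2 (0.38, edgeR adjusted p = 0.0385) and Ptgis (0.25) rose and the transporter Slco2a1 fell (-0.31). With the length correction Ptgs2 and Ptges2 were the members past the threshold, and Ptgis was at 0.15 and Slco2a1 at -0.13.

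Cytokine and NF-kappaB response genes split. Of 16 tested, 2 rose, Il6 and Cxcl1, and 5 rose and 4 fell when adjusted over the list alone. In the paired fit 6 rose, among them the chemokine Cxcl5 (1.29) and Saa3 (2.27), and 3 fell, namely Tnfaip3, Icam1 and Vcam1 (-0.47), with 6 and 4 after the length correction. The list as a whole did not pass camera (adjusted p = 0.332, paired 0.0827; 0.751 and 0.536 with an estimated correlation). It passed fry unblocked (0.0397) but not in the paired fit (0.111). Paired camera with pair 1, 2 or 3 left out gave 0.00171, 4.31e-06 and 0.0444, the second with a list median of -0.0487. Secreted growth factors and antagonists moved up by camera (adjusted p = 0.0177, paired 0.0219, adjusted p = 0.605 with an estimated correlation), but not without vehicle library 3 (0.0846) or PGE2 library 3 (0.0752), nor in the paired fit without pair 3 (0.118). Il6 was the member of its 17 that rose unblocked, and 5 rose when adjusted over the list alone. In the paired fit 6 rose, including the hepatocyte growth factor Hgf (0.76), Vegfa (0.54) and Lif (0.66), and 2 fell, Igf1 (-0.26) and Igf2, or 7 and 2 with the length correction, where Igf1 was at -0.09 and did not pass.

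Contractile and TGF-beta response genes of myofibroblasts moved up by camera (adjusted p = 4.79e-06, paired 5.11e-07, adjusted p = 0.605 with an estimated correlation). Of 15 tested, 1 rose unblocked, 9 rose when adjusted over the list alone, and 10 rose in the paired fit. Smooth muscle actin Acta2 (0.85, from 534 ± 124 to 955 ± 187 CPM) and Myl9 (1.11) rose in the paired fit. With the length correction 7 members rose. Acta2 went from 0.85 ± 0.157 to 0.74 ± 0.252 and Myl9 from 1.11 ± 0.125 to 0.92 ± 0.232. With these smaller changes and wider errors neither passed (edgeR adjusted p = 0.2 and 0.131). Fibrillar matrix genes had 0 of 18 past the threshold, 1 higher and 1 lower when adjusted over the list alone. In the paired fit Lox, Loxl1 (0.44) and Loxl2 (0.38), which cross-link collagen, rose, and Col6a1, Col6a2, Col6a3 (-0.86), Eln and Postn fell, with 5 in each direction after the length correction. Matrix proteases and inhibitors had 2 of 18 higher, including the urokinase gene Plau (0.71), and 6 higher and 3 lower when adjusted over the list alone. The paired fit had 8 higher and 4 lower, including Timp1 (0.85 ± 0.101) up and Timp3 (-0.53) down, or 7 and 4 with the length correction, where Timp1 was at 0.63 ± 0.146 (edgeR adjusted p = 0.054). Neither of these lists passed camera (adjusted p = 0.727 and 0.336), but in the paired fit the matrix list passed without pair 3 (0.0271) and the protease list without pair 1 (0.0304) or pair 2 (0.00189).

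Markers of the progenitors themselves went both ways. Of 18 tested 0 passed unblocked, 3 higher and 2 lower when adjusted over the list alone. In the paired fit Thy1 (0.73), Ly6a (0.62), Cd55 (0.62) and Pi16 rose and Col15a1, Cd34, Gsn (-0.44), Lum and Mme fell, or 7 and 6 after the length correction (Mme then at -0.13, after -0.33, and not past the threshold; camera adjusted p = 0.936; the list's median was -0.017 and its mean 0.0279). Adipogenesis genes had 0 of 15 past the threshold, 2 higher when adjusted over the list alone. In the paired fit the early regulators Cebpb (0.60) and Cebpd (0.57) and Fabp4 rose, while Pparg, Adipoq (-1.12), Plin1, Plin4, Cd36 and Cfd (-1.50) fell, with 4 and 6 after the length correction (Plin4 then at -0.56, after -0.70, and not past the threshold; camera adjusted p = 0.918, with a median of 0.0409 and a mean of -0.232). Bone and cartilage genes had 0 of 10 unblocked, 1 higher and 2 lower when adjusted over the list alone. By the paired fit osteopontin Spp1 (0.82) rose and Sox9 (-0.46), Bmp2 (-1.13) and Col2a1 fell, with 1 and 3 after the length correction. Wnt pathway genes had 0 of 16 in both counts unblocked, and 2 higher and 3 lower in the paired fit, among the latter Rspo2 (-0.81), or 2 and 3 after the length correction. Neither list passed camera (adjusted p = 0.644 and 0.719).

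None of 16 genes of G2 and M phase passed unblocked, over all genes or adjusted over the list alone, and in the paired fit 7 fell, including Cenpe (-0.81), Cenpf (-0.82) and Mki67 (-0.68), or 10 with the length correction. Camera gave an adjusted p of 0.158 unblocked and 2.78e-05 in the paired fit (paired, adjusted p = 0.536 with an estimated correlation), and unblocked it was 0.018 without vehicle library 2 and 9.79e-05 without PGE2 library 1. The list's paired fold changes followed transcript length across its 16 genes (rho = -0.685, permutation p = 0.0042), and its median difference was -0.258, 0.00112 and -0.597 in pairs 1 to 3. The permutation shuffled the 16 genes as if independent, while their estimated correlation was 0.964, so its p only describes these genes. Of 15 S phase genes 0 passed unblocked in both counts and 2 fell in the paired fit, Mcm6 (-0.26) and Rrm1 (-0.27), or 1 higher and 4 lower with the length correction, where Rrm1 was at -0.17 and did not pass (camera adjusted p = 0.911, but 0.0483 and upward without vehicle library 1). Of 12 p53 and growth arrest genes 0 passed unblocked, 1 higher and 2 lower when adjusted over the list alone. The paired fit raised Gadd45b and Gadd45g (0.97) and had 5 lower, among them Trp53inp1 (-0.64), or 2 and 7 with the length correction. Of 16 apoptosis genes 0 passed unblocked in both counts and 2 fell in the paired fit, or 4 with the length correction (camera adjusted p = 0.347 and 0.303). The paired camera test called these lists down with the length correction (adjusted p = 0.0456 and 0.02) and not without it (0.278 and 0.141; paired adjusted p = 0.821 and 0.567 with an estimated correlation and no length correction).

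Endoplasmic reticulum and amino acid stress genes had 0 of 10 past the threshold in both counts, and 5 rose in the paired fit, including the chaperone Hspa5 (0.47) and Xbp1 (0.40), or 4 with the length correction. Hypoxia and glycolysis genes had 0 of 13, 1 when adjusted over the list alone, and 4 rose in the paired fit, including Pfkfb3 (0.63) and Bnip3 (0.59), or 5 with the length correction. Both moved up by camera (adjusted p = 0.0177 and 0.0151, paired 0.00044 and 0.000969, but adjusted p = 0.769 with an estimated correlation for each). The stress list did not pass unblocked with the length correction (0.0688; median 0.198, from 0.327), without vehicle library 1 (0.0594) or without PGE2 library 3 (0.239), and the hypoxia list not without vehicle library 3 (0.165) or PGE2 library 1 (0.136). Interferon response genes moved down by camera (adjusted p = 0.0177, paired 0.0115, adjusted p = 0.823 with an estimated correlation), yet 0 of 12 members passed in either fit or when adjusted over the list alone, and the list's median difference was -1.77, 0.455 and -0.222 in pairs 1 to 3. That list did not pass without vehicle library 1 (0.179), vehicle library 3 (0.162) or PGE2 library 1 (0.258), or in the paired fit without pair 1 (0.939). Cholesterol synthesis genes had 0 of 12 in either fit and when adjusted over the list alone, and 1 fell in the paired fit with the length correction (camera adjusted p = 0.812).

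Markers of other cell types moved as well. Of 10 myogenic genes tested 0 passed unblocked, over all genes or adjusted over the list alone, and in the paired fit 6 fell, including the muscle regulator Myod1 (-1.35) and Myh8 (-1.17), or 5 with the length correction (camera adjusted p = 0.0695, paired 6.61e-07, paired adjusted p = 0.536 with an estimated correlation; unblocked 0.0377 without vehicle library 2 and 8.43e-07 without PGE2 library 1). Myh8 did not pass with that correction, at -1.003 ± 0.347 after -1.17 ± 0.253. The geometric mean of these genes was 14.8, 4.62 and 3.35 CPM in vehicle libraries 1 to 3 and 10.6, 1.5 and 1.42 CPM in PGE2 libraries 1 to 3. In the paired fit 4 of 8 pericyte and smooth muscle genes fell, among them Cspg4 (-0.84), with 1 left after the length correction. Of the others Rgs5 was at -0.92 ± 0.253 after -0.95 ± 0.231, Des at -1.02 ± 0.311 after -1.002 ± 0.239, and Notch3 at -0.27 ± 0.096 after -0.47 ± 0.1. The same fit had 2 of 5 Schwann cell genes lower, S100b and Cdh19, 1 of 6 endothelial genes lower, Tek, and 1 of 6 tendon cell genes lower, Thbs4, with the same counts after the length correction. Of 4 macrophage and leukocyte genes tested, Csf1r and Cd14 rose in the paired fit and were at 1.89 and 8.10 CPM under PGE2; Csf1r alone passed with the length correction, where Cd14 was at 0.30 after 0.44. None of these 5 lists passed camera (adjusted p between 0.104 and 0.911), though the pericyte and smooth muscle list passed in the paired fit without pair 1 (0.0234) or pair 2 (0.00618). The macrophage and leukocyte list passed fry unblocked (0.00878) and not in the paired fit (0.134), with median differences of 0.272, 0.265 and 0.262 in pairs 1 to 3. Unblocked, 0 of their members passed over all genes, and when adjusted over the list alone 2 macrophage and leukocyte genes rose and 2 Schwann cell genes fell.

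**Figure D3:**
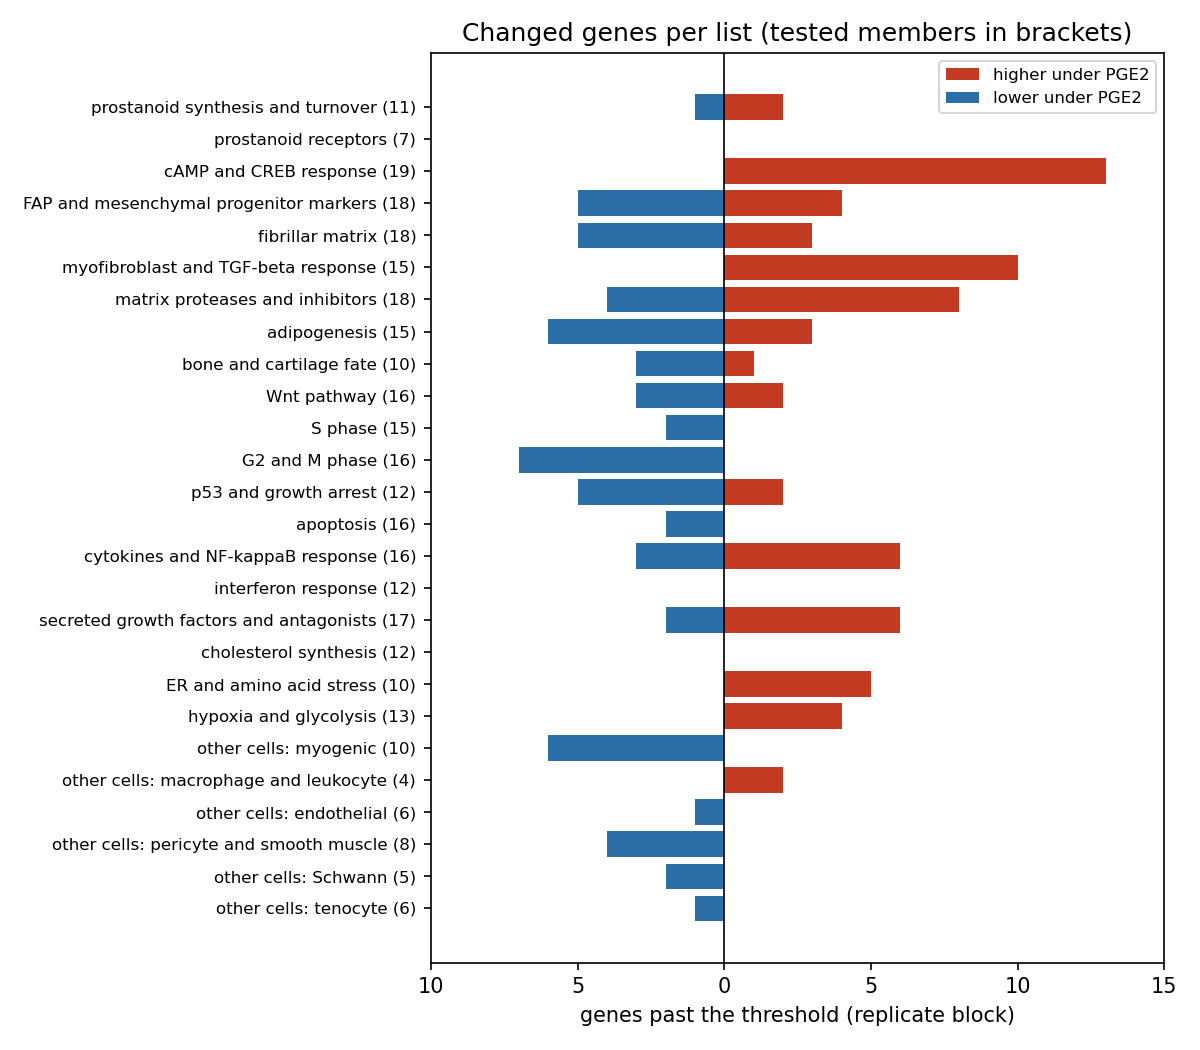
Number of genes past the threshold in the paired fit for each of 26 lists, with higher genes drawn to the right of 0, lower genes to the left and the number of tested members in brackets. The cyclic AMP and CREB list has 13 higher and none lower, and the G2 and M phase list has 7 lower and none higher.

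Camera with the preset correlation called 6 of 26 lists, 8 in the paired fit and 0 with an estimated correlation in either fit. It called 3 without vehicle library 3 and 4 without PGE2 library 3. Of the 10 ways to divide the 6 libraries into groups of 3, 6 gave at least 6 lists, and the highest gave 15, so the number of lists called did not set the real grouping apart. The cyclic AMP and CREB list had a smaller camera adjusted p under the real grouping than under any other, the lowest of which was 0.000256. The same held for the secreted growth factor list (0.0177, lowest other 0.052), but among paired groupings another reached 0.0078 for it. It also held for the cytokine and the macrophage and leukocyte lists, which camera did not call. With 10 groupings a list can be smallest under the real one by chance, so this ranking alone does not set a list apart. Each adjusted p also depends on the other lists tested under the same grouping. For the myofibroblast list another grouping reached 1.49e-08.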

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

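The correction for length or GC content, thinning, the myogenic covariate, pairs left out and the combinations with the block were chosen after the data were seen; the other settings were planned. All 52 genes kept their direction under every setting with a value for them, except that 51 had one under the filter of 10 counts in all libraries. Counts are all, higher, lower and at least 2-fold, against 52, 32, 20 and 27. They were 829, 388, 441 and 140 with DESeq2, 13, 7, 6 and 7 with limma-voom, and 285, 143, 142 and 66 with no filter. Scaling by library totals gave 34 lower, the adjusted p threshold of 0.01 gave 0 of each with 3049 genes at an unadjusted p under 0.05, and the test against a 1.2-fold change gave 8, 3, 5 and 7. Length correction gave 12, 6, 6 and 8, and the myogenic covariate 676, 314, 362 and 136. Leaving out 1 library gave 0 to 120, 0 to 85, 0 to 35 and 0 to 70. RLE size factors (50), GC correction (56) and thinning (72) stayed within 1.5 times. The cause of these shifts was not tested.

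With the replicate block the counts were 2189, 1049, 1140 and 249. With the block they were 2576, 1267, 1309 and 214 after length correction, 2210, 1002, 1208 and 249 after GC correction, 1921, 883, 1038 and 199 by DESeq2, 2174, 1019, 1155 and 254 by limma-voom, and 2068, 1002, 1066 and 204 after thinning. Leaving out pair 1 from the blocked fit gave 1372, 669, 703 and 307, and leaving out any pair gave 1160 to 5097, 489 to 2392, 671 to 2705 and 224 to 323, the most without pair 3. The block moved 58 named genes past the threshold and, by camera, 2 lists, and ended no call of a named gene or of a list by camera. DESeq2 moved 30 named genes past the threshold.

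Lists called were 6, 0 by camera with an estimated correlation with or without the block, and 10 with the block and length correction. Fry called 4 without the block, and with it the smallest fry adjusted p of any list was 0.111. By fry the cyclic AMP and CREB list went from 0.00608 to 0.111 and the secreted growth factor list from 0.0202 to 0.171. By camera, leaving out 1 library gave 3 to 8 lists, or 9 to 11 with the block and 1 pair left out. Without vehicle library 1 the S phase list passed upward with a median of 0.173, against -0.0713 and not past the threshold with all libraries; over the libraries left out its median ranged from -0.321 to 0.173. In the shallowest library, vehicle 2, 3 counts corresponded to 0.142 CPM, which limits genes near that level such as Ptger2.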

Other observations

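The tests of explanations in this part, and its lists of acute phase, lipid transporter, retinoid and imprinted genes, were chosen after the result was seen. These lists hold genes that prompted them, so member counts and no list tests are given. Of 26 tested genes of the acute phase and STAT3 response, which interleukin 6 family cytokines induce, 0 passed unblocked and 20 rose in the paired fit with none lower, or 22 with the length correction. The feedback inhibitor Socs3 rose by 0.82, the acute phase genes Saa3 by 2.27 and Hp by 1.34, and the metallothionein Mt1 by 0.86 on the log2 scale. Some members also stand in the lists fixed beforehand. Stat3 itself was at 0.06 and passed with the length correction alone, and C3 (-0.14) and Il6ra (-0.04) did not pass in either paired fit.

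The neighbouring lipid transporter genes Abca5, Abca6, Abca8a, Abca8b and Abca9 all fell in the paired fit, with and without the length correction, and Abca6 and Abca8a also unblocked. Of 17 retinoid genes, Rdh10 rose unblocked, and in the paired fit 6 rose, including Aldh1a2 (0.76) and Crabp2 (1.18), and 3 fell, including Adh1 (-1.14), with 6 and 4 after the length correction.

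Longer transcripts were lower under PGE2. GC content and depth as the whole source are argued against by rank correlations that stayed near the -0.512 of the uncorrected unblocked fit. They were -0.477 after GC correction in the paired fit and -0.507 after thinning in the unblocked fit. The trend as the whole source of the paired calls is argued against by the 1690 of 2189 that were shared after its removal. RNA integrity or library preparation may set the trend: its slope ranged by 0.12 among vehicle libraries alone, and pair 3 nearly lacked it. That source and a response to PGE2 cannot be told apart, since no integrity measure was analysed here.

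Myogenic markers were lower within all 3 pairs for 9 of 10 tested genes. A smaller share of myogenic cells under PGE2 may account for this, or lower expression in such cells, and the 9 genes leave both open because each would lower them together. With the myogenic score, the mean log2 CPM of that list, as covariate, all 52 unblocked calls still passed in the same direction, among 676 genes. That fit cannot settle whether such cells were the whole source of these calls. The score overlapped between the groups, while the 52 genes had groups that did not overlap.

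Of 29 imprinted genes tested, 10 fell and 1 rose, Nnat, in the paired fit, or 8 and 1 with the length correction. Over all 29 the median was -0.206, or -0.189 with the length correction. The 10 that fell had a median log2 fold change of -0.81, ranging from -1.19 to -0.353, and include Peg3, Peg10, Mest, Plagl1 and Cdkn1c. The length trend as the whole source is argued against by the median over all 29, which changed little with the correction. For the 10 the median was -0.795 after length correction, but they were picked as lower, so that value is not counted as support. With the myogenic covariate, in a fit with no block, the median of the 10 was -1.02. Myogenic cells cannot be excluded by it, since the 10 were picked as lower and the score overlapped between the groups. These medians of the 10 replaced list tests on the same fits once the other groupings of the libraries had been seen. Among the 10, Igf2r shrank from -0.38 ± 0.103 to -0.16 ± 0.0619 with the length correction and Igf2 from -0.66 to -0.26 with the covariate. Neither Igf2 nor Igf2r (-0.31) passed with the covariate (edgeR adjusted p = 0.123 and 0.143). Dlk1 also no longer passed with the length correction, at -0.93 ± 0.226 after -0.99 ± 0.13. A hypothesis that PGE2 lowers a set of imprinted growth regulators stays open beside RNA quality and myogenic cells, and the members Meg3 (-0.12) and H19 (-0.48) did not pass the paired test.

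The 6 libraries divide into groups of 3 in 10 ways, too few for a share under 0.05. The real grouping, 1 of the 10, changed 52 genes and the highest other changed 0. Before adjustment the contrast was smaller. At an unadjusted edgeR p under 0.05 the real grouping had 3049 genes, and that of vehicle 1, vehicle 2 and PGE2 1 had 2462. Among the 4 that part every pair, the real one changed 2189 genes in the paired fit, again 1 of 4, and the highest other changed 0. Of the list tests, 6 of 10 groupings called at least the 6 lists of the real one, with a highest other of 15, and 2 of 4 paired groupings called at least its 8, with a highest other of 9. The grouping with 15 lists set vehicle 1 with PGE2 1 and PGE2 2 and points to structure among the libraries apart from treatment.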
